A study of Carassius auratus with 4 samples.

How the data were processed

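The data came from cDNA arrays of goldfish (Carassius auratus) carrying 8100 different clones, each printed in 2 spots over 48 print blocks. Each of the 4 arrays was hybridised with RNA of dispersed pituitary cells given 10 nM goldfish secretoneurin for 12 h and with RNA of control cells, which the labels describe as having had no incubation. Per the labels, total RNA was extracted with TRIzol, treated with DNase on a column, checked for integrity and labelled with a Genisphere detection kit. Secretoneurin RNA carried Cy5 on replicates 1 and 3 and Cy3 on replicates 2 and 4. The dye of each image and the image marked as control in the file headers gave the same orientation on all 4 arrays.

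The deposited scanner files hold, per the file headers, the linear intensity of each spot and its local background in both channels, neither background subtracted nor corrected for crosstalk between the dyes. They also hold the standard deviation of the background and a mark for spots to be ignored. The authors' deposited value table holds log2 ratios, whose method of calculation is not given in the sources used here. Its columns were taken as Cy5 over Cy3 and had array medians of 0.016, 0.047, 0.020 and -0.032. The normalization stayed unknown, and the table served only as an alternative source of values.

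Background was corrected with normexp at an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess over the whole array (span 0.3, 4 iterations), in limma 3.58.1 under R 4.3.3. Spots that the scanner software marked to be ignored (421, 720, 981 and 718 on replicates 1 to 4) and 1128 control or empty spots per array had no weight in the loess fit and entered no test. The spots of a clone were averaged, and 8089 probes with a value on at least 3 arrays were tested. A channel of a probe was called well above background when its signal exceeded the background plus 2 background SDs. By that measure 839 probes were above background in both channels on all 4 arrays, and 1105 probes (13.7%) in no channel on any array. Of the named probes, 25 were not well above background on any array in 1 group only, 24 of them in control cells and 1 in secretoneurin cells. Raising the dim group to the lowest signal that was above background on each array, in channel values after loess and Aquantile scaling, changed the ratio of 6 of them. For the others it gave the fitted ratio again, which is no bound, so no fold is given for these probes. The ratios of 1 of them on single arrays, in the closing section, are not measured folds. This mark does not show that a transcript was absent from a group. At least 1 channel was above background in 57.7%, 49.0%, 73.3% and 44.2% of gene spots on replicates 1 to 4, so it varied between arrays. The initiation factor 4 gamma 1 probe was marked in control cells although its mean log2 signal was 8.30 there and 8.03 in secretoneurin cells.

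Every ratio was turned to secretoneurin over control. The limma fit (lmFit and eBayes, two-sided) held the secretoneurin effect and a probe-specific dye effect, which left 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The dye effect was tested in the same fit. Gene names are those of the array design, found for 3307 probes with 2166 different names. Of these, 97 names hold a RefSeq protein accession, and 0 of the accessions occurred in the goldfish reference table, so the names were kept as printed. Different probes of a gene were tested separately.

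The 24 gene lists covered pituitary hormones, granins and prohormone processing, exocytosis, G protein, calcium, cAMP and protein kinase C signalling, immediate early genes, receptors of the reproductive axis, dopamine and GABA, ribosomal proteins, translation factors, oxidative phosphorylation, glycolysis, ER chaperones, cytosolic heat shock proteins, proteasome and ubiquitin, antioxidant enzymes and iron, cytoskeleton, cell cycle, and cholesterol and lipid. They also covered markers of red blood cells, muscle, leukocytes, neural and glial cells, connective tissue and endothelium, epithelium and liver. The lists held 1033 probes. Wrong or missed matches were corrected from the probe names alone, before any model was fitted. Lists with at least 5 probes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry (directional and mixed) beside it.

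The comparisons, the lists, the rule for named probes and the alternatives were fixed before the data were examined, apart from those said to have been added later. The rule took up to 15 named probes per direction past the threshold with 1 direction on all 4 arrays, ranked by absolute log2 ratio with 1 probe per gene name. Where fewer than 10 qualified, it was filled to 10 with the named probes of smallest unadjusted p and 1 direction on all 4 arrays. It also took every member of the hormone and granin lists, and for each other list the members past the threshold or otherwise the 3 of smallest unadjusted p. It named 94 probes.

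The procedure was tested on simulated data with 8089 probes and 200 changed probes. Their noise was independent, with the SD that limma fitted for each probe, equal on all 4 arrays. It recovered 38 of 71 probes changed by 0.5 on the log2 scale, 63 of 67 changed by 1 and 60 of 62 changed by 2, with 15 false among 176 calls. With no effect it made 0 calls with limma, beside 359 at an unadjusted p under 0.05. The real log2 ratios had SDs of 0.20, 0.32, 0.19 and 0.38 on replicates 1 to 4, and replicates 2 and 4 opposed each other. The simulation held neither trait, so its recovery is not the power of these arrays. Alternatives covered background correction, the loess, scaling, the dye effect, dim and ignored spots, array weights, the authors' table, moderation, the threshold, an unmoderated test, duplicate spots, the set test, 1 probe per gene name and each array left out. Added after the data were seen were the turned sign of replicate 4 or 2, averaging of probes with the same gene name, and each array left out in a fit with no dye effect. Figures were drawn with matplotlib 3.10.9.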

Results

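Dispersed cells from male and female goldfish pituitaries were exposed to 10 nM goldfish secretoneurin, a peptide cut from the granin protein secretogranin II, and their RNA was compared with that of control cells. The series describes 4 control and 4 treatment samples, which were paired on 4 arrays with the dyes exchanged on replicates 2 and 4. Each array had 16200 gene spots. Both channels lay above background in 18.9%, 16.9%, 17.8% and 15.9% of these on replicates 1 to 4, against 0.298%, 0.595%, 0% and 0.298% of the empty spots. Median Cy5 intensities were 221, 218, 156 and 206 and median Cy3 intensities 591, 653, 400 and 524 scanner units. Over the 4 arrays the median SE of a log2 ratio was 0.071, and the median half-width of its 95% confidence interval was 0.19. The labels do not say whether the sample pairs came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

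The main comparison asked which transcripts differed after 12 h with secretoneurin. No named gene passed the test, and the probes below are those of smallest unadjusted p with 1 direction on all 4 arrays. On the lower side, NDRG4, a protein of neural tissue, had a log2 ratio of -0.37 ± 0.088 (SE, 4 arrays). It passed only without replicate 4 (-0.47), where replicate 2 is alone in its dye orientation and its spread was not measured. A tetraspanin-3 probe, for a membrane protein, had one of -0.29 ± 0.054, and a probe of 60S ribosomal protein L7 one of -0.29 ± 0.062. A SUMO-2 probe (small ubiquitin-related modifier 2) stood at -0.25 ± 0.058, the zinc finger protein Rabring 7 (probe 23j15) at -0.27 ± 0.054, the mitochondrial ADP/ATP translocase 1 at -0.24 ± 0.055, and 1 probe of secretogranin II, the precursor of secretoneurin itself, at -0.25 ± 0.061. On the higher side, the leucine zipper-EF-hand containing transmembrane protein 1 had a log2 ratio of 0.27 ± 0.065, 1 probe of fumarate hydratase, an enzyme of the citric acid cycle, one of 0.21 ± 0.055, and Kelch domain containing protein 1 one of 0.19 ± 0.056. These are single probes, and averages over all probes of a name, added after the data were seen, were smaller for several. They were -0.24 for 2 NDRG4 probes, -0.18 for 2 of Rabring 7, -0.097 for 3 of tetraspanin-3, -0.12 for 3 of L7 (0.02 on replicate 2), -0.018 for 5 of SUMO-2 (0.23 on replicate 2) and 0.058 for 5 of fumarate hydratase (-0.084 on replicate 2).

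The other probes of this group were not well above background on any array in at least 1 group. Several of those given above were near background too. The leucine zipper-EF-hand and Kelch probes were above it on 1 array in each group. Fumarate hydratase was above it on 2 arrays in secretoneurin and 1 in control cells, and tetraspanin-3 on 2 in each group. Control signal was not well above background on any array for 7 of the 10 higher probes, so their ratios are not measured folds and none is given. Among those with ratios above 0 on all 4 arrays were a probe of EPD (ependymin, a glycoprotein of the teleost brain), of which the 14 probes of that name averaged 0.028, and probes of the metalloproteinase inhibitor TIMP-3 and dopamine-beta-hydroxylase, which makes noradrenaline. Probes of anion exchange protein 2 and an RNA polymerase II coactivator had the same direction. Cytochrome c oxidase polypeptide VIc had ratios below 0 on all 4 arrays and was not well above background in secretoneurin cells. It passed only without replicate 2, where replicate 4 is alone in its dye orientation. The dopamine D1 receptor (drd1), the transitional endoplasmic reticulum ATPase and a glutaminase-like probe were not well above background in either group, and an FXYD domain probe was not in control cells. The adjusted p was 0.998 for all 20 of these probes in limma. Of the 10 lower probes, 3 (L7, SUMO-2 and NDRG4) were above background in both channels on all 4 arrays, and of the 10 higher probes 0 were.

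**Figure D1:**
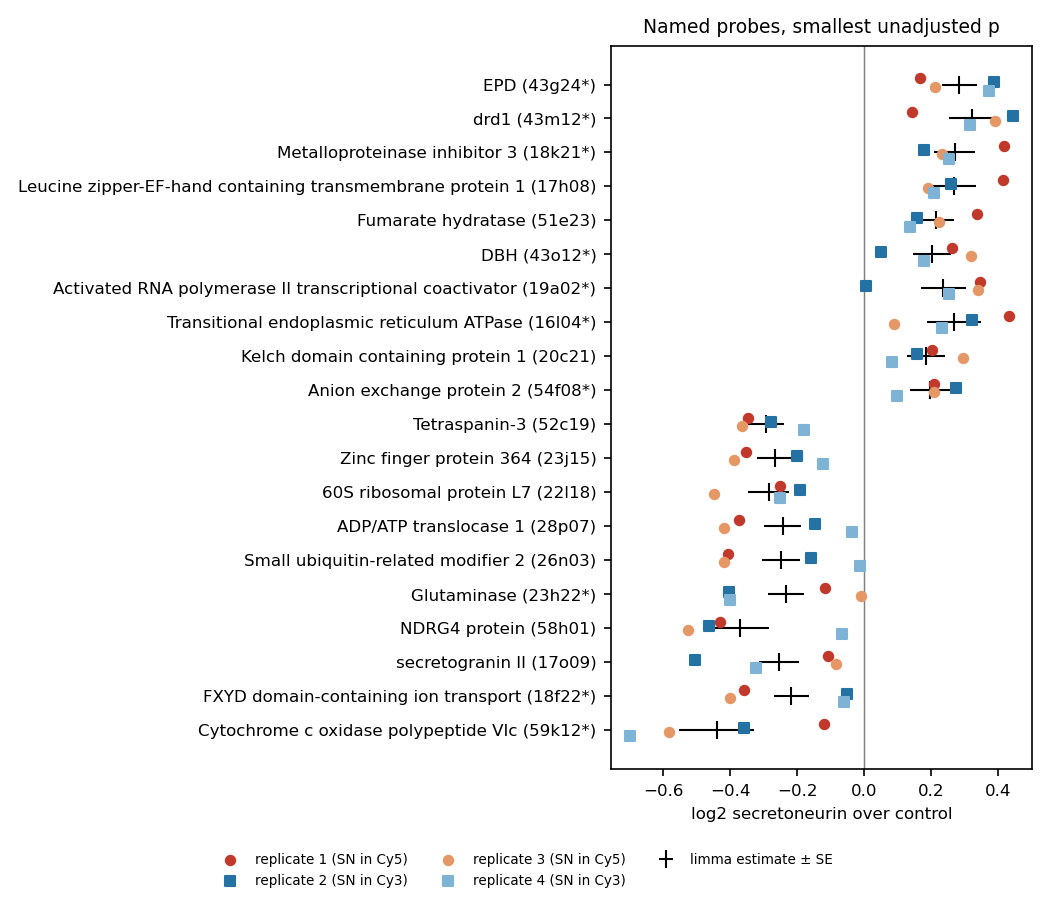
Log2 ratio of secretoneurin over control (x axis) for the 20 named probes of smallest unadjusted p with 1 direction on all 4 arrays (y axis, clone in parentheses). Circles are arrays with secretoneurin in Cy5, squares those with it in Cy3, and black bars the limma estimate with its SE. An asterisk marks a probe not well above background on any array in at least 1 group, whose ratio is not a measured fold. NDRG4 runs from -0.53 to -0.07, and no probe of the plot passed the adjusted threshold.

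Over all 8089 probes, limma called 0 higher and 0 lower, with a smallest adjusted p of 0.998. At an unadjusted p under 0.05 there were 97 higher and 127 lower probes, 224 in all where 404 would be expected by chance, and an unmoderated test also called 0, with 116 higher and 166 lower unadjusted. The unadjusted split moved to 55 higher and 127 lower with print-tip loess and to 97 higher and 62 lower in the authors' deposited table, and was 1 higher and 21 lower among the 839 probes above background. Estimates ran from -0.45 to 0.85, and 852 probes (411 higher, 441 lower) had 1 direction on all 4 arrays. That was 10.7% of the probes measured on all 4, where chance gives 12.5% for independent arrays with no dye effect. Replicates 2 and 4 opposed each other, so neither this share nor the 404 probes is an exact baseline here. The count of 0 depended on replicates 2 and 4: without replicate 2 limma called 346 probes (38 higher, 308 lower), and without replicate 4 it called 438 (420 higher, 18 lower), and 261 probes were lower in the first and higher in the second. In each of these fits the remaining array with secretoneurin in Cy3 is alone and is assumed to vary like the others. With no dye effect as well, an alternative added after the data were seen, limma called 0 in both cases. Unadjusted there were 136 higher and 114 lower without replicate 2 and 285 higher and 149 lower without replicate 4.

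Pituitary hormones were measured by 4 probes, and these had limma estimates near 0. Growth hormone stood at -0.062 ± 0.060 (SE, 4 arrays) and a carp somatotropin probe, also growth hormone, at -0.049 ± 0.10. Gonadotropin GTH-II stood at -0.043 ± 0.072 and the beta subunit of thyrotropin at -0.0048 ± 0.052. The GTH-II probe was above background on only 2 arrays in secretoneurin and 1 in control cells. Its mean log2 brightness was 8.15, like that of the buffer spots (8.15), so its estimate near 0 does not show an unchanged transcript. The somatotropin estimate turned to 0.090 with print-tip loess and to 0.029 in the authors' table. All 4 hormone probes were higher in whichever RNA carried Cy5: growth hormone ratios were 0.33, -0.43, 0.43 and -0.58 on replicates 1 to 4. The list was too short for a set test.

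The 11 probes of granins and prohormone processing had a median log2 ratio of -0.055, with 9 below 0 and 2 above (camera adjusted p = 0.235). After median centring without loess the median was -0.13 and the adjusted p 0.000774, and with 1 probe per gene name the adjusted p was 0.0442. The 7 secretogranin II probes disagreed. Probe 17o09 was below 0 on all 4 arrays, with ratios of -0.11, -0.51, -0.08 and -0.32 (limma unadjusted p = 0.0127), and probe 51n02 was above 0 on all 4, at 0.11 ± 0.053. Probes 42j04, 42e10, 53n16 and 42e09 stood at -0.13, -0.057, -0.059 and -0.036, and probe 52l24 at 0.047, below 0 with print-tip loess, median centring or the authors' table. Carboxypeptidase E, which trims prohormones, was below 0 on all 4 arrays in probe 52l20, at -0.12 ± 0.054 (limma unadjusted p = 0.0940), and its probe 15o22 was not well above background in control cells. Secretogranin III stood at -0.055 ± 0.057, and secretogranin V at -0.0072 ± 0.095, above 0 with print-tip loess and in the authors' table. None of these probes passed over all genes or adjusted over the list alone, where the smallest adjusted p in limma was 0.139.

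**Figure D2:**
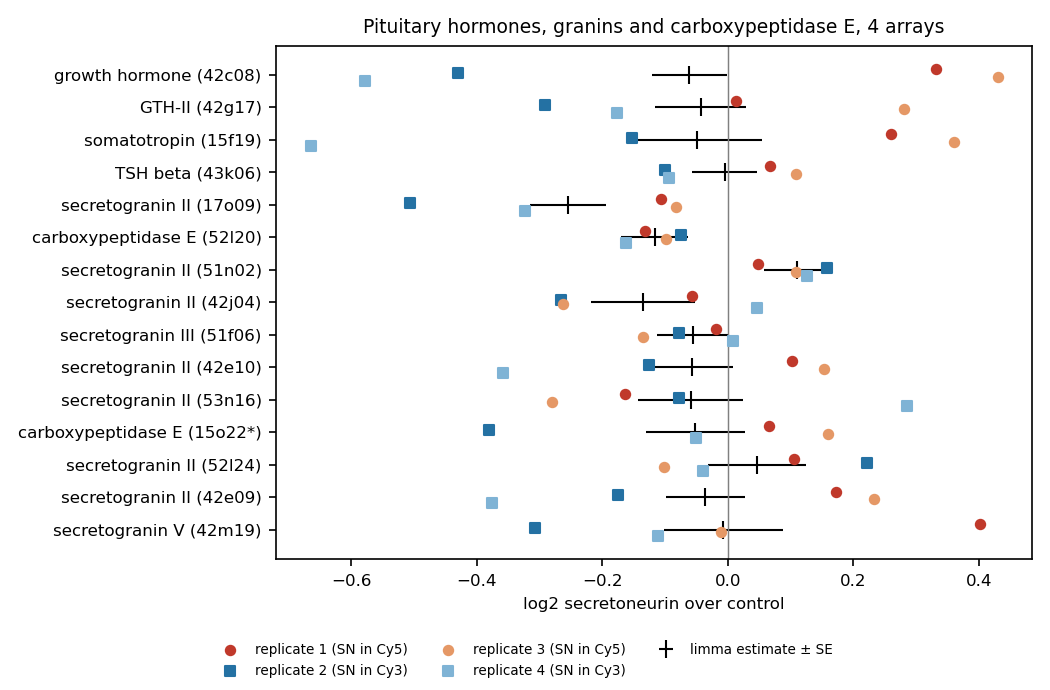
Log2 ratio of secretoneurin over control (x axis) for every probe of the hormone and granin lists (y axis, clone in parentheses). Circles are arrays with secretoneurin in Cy5, squares those with it in Cy3, and black bars the limma estimate with its SE. The asterisk marks a probe not well above background on any array in control cells. The growth hormone circles lie at 0.33 and 0.43 and its squares at -0.43 and -0.58.

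Genes of secretion and signalling showed no called shift. The 37 exocytosis probes had a median of -0.010 (adjusted p = 0.691, camera here and below), with syntaxin-4 at -0.16 ± 0.066 (SE, 4 arrays), complexin-1 at -0.14 ± 0.067 and a SNAP-25B probe not well above background in control cells (the 4 SNAP-25B probes averaged 0.022). The 61 signalling probes had a median of -0.0044 (adjusted p = 0.727), with 3 calmodulin probes, for the calcium sensor, in front at -0.21 ± 0.059, -0.17 ± 0.058 and -0.16 ± 0.055, where the 28 calmodulin probes averaged -0.032. The 7 immediate early probes had a median of 0.044 (adjusted p = 0.395). Their jun-B probe 55o22 stood at -0.16 ± 0.10, junB probe 15i19 was not well above background in either group, and the anti-proliferative BTG1 was not well above background in control cells. The 47 probes of reproductive, dopamine and GABA receptors had a median of 0.014 (adjusted p = 0.395), led by drd1, dopamine-beta-hydroxylase and the dopamine D3 receptor, none of them well above background in control cells.

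Ribosomal protein genes gave the 1 list called by camera of the 22 tested. The median of their 115 probes was -0.051, with 86 below 0 and 29 above (adjusted p = 0.000599, camera). With an estimated correlation the adjusted p was 0.600. That correlation was 0.012, close to the preset 0.01, but this form of camera rests on the 2 residual degrees of freedom. It called 0 of the 22 lists, so the loss of the call says little about this one. Fry, which tests the list against no change rather than against other genes, gave an adjusted p = 0.833. Besides L7, ribosomal proteins L23 and L6 stood at -0.17 ± 0.052 (SE, 4 arrays) and -0.27 ± 0.073 (SE, 3 arrays). The list's median on single arrays was -0.22, 0.08, -0.14 and 0.07 for replicates 1 to 4, thus below 0 only where secretoneurin carried Cy5. The adjusted p was 0.255 without replicate 1, 0.0612 without replicate 2 and 0.107 without replicate 4. The 31 translation factor probes had a median of -0.024 (adjusted p = 0.235, and 0.0442 with 1 probe per gene name), with elongation factor 1 alpha at -0.13 ± 0.052. Probes of initiation factors 1A and 4 gamma 1 were not well above background in control cells.

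Metabolic genes were not called as lists. The 77 probes of oxidative phosphorylation had a median of -0.014 (adjusted p = 0.727, camera), and besides oxidase polypeptide VIc its first members were ubiquinol-cytochrome c reductase core protein 2 and cytochrome c1, which were not well above background in control cells; the 2 probes of each name averaged 0.070 and 0.074. The 80 glycolysis probes had a median of -0.022 (adjusted p = 0.395), with aldolase A at -0.25 ± 0.071 (SE, 4 arrays), aldolase C at -0.19 ± 0.058 and GAPDH at -0.19 ± 0.072. Over all probes of these genes, spelling variants of the name included, the averages were -0.089 for aldolase A (4 probes), -0.0030 for aldolase C (22 probes) and -0.046 for GAPDH (14 probes). The 12 cholesterol and lipid probes had a median of -0.0038 and a mean of -0.0012 while camera pointed up (adjusted p = 0.872). Apolipoprotein Eb probes stood at 0.17 ± 0.068 and -0.18 ± 0.13, a further one was not well above background in control cells, and all 17 averaged -0.024.

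Genes of protein folding, turnover and stress were likewise not called. The 13 ER chaperone probes had a median of -0.058 (adjusted p = 0.395, camera), with the translocon-associated proteins alpha and delta at -0.14 ± 0.064 (SE, 4 arrays) and -0.086 ± 0.057 and disulfide isomerase A3 not well above background in control cells. The 47 heat shock probes had a median of -0.0050 (adjusted p = 0.691), with HSP90-beta probes 42j13 and 14k03 at -0.18 ± 0.064 and -0.17 ± 0.069 (all 10 averaged -0.091) and the constitutive HSC70-2 at -0.14 ± 0.058. The 92 proteasome and ubiquitin probes had a median of 0.0017 and a mean of -0.011, with camera pointing down (adjusted p = 0.395). Proteasome subunit alpha 2 stood at -0.21 ± 0.059, the ubiquitin ligase TRAF7 at -0.15 ± 0.062 and uch-L1 at -0.12 ± 0.052. The 42 probes of antioxidant enzymes and iron had a median of -0.011 (adjusted p = 0.588), which was -0.080 without replicate 2 (adjusted p = 0.00264), 0.045 without replicate 4 (adjusted p = 0.173) and 0.0049 without replicate 1. Its first members were ferritin heavy chain at -0.22 ± 0.091, glutathione S-transferase A at -0.22 ± 0.11 and glutathione S-transferase alpha 1 at -0.16 ± 0.096. The 3 ferritin heavy chain probes averaged -0.025 and the 4 of glutathione S-transferase A -0.090. The 88 cytoskeleton probes had a median of -0.014 (adjusted p = 0.797), with a beta actin 1 probe at -0.19 ± 0.057 (14 beta actin probes averaged -0.035), a stathmin family clone at 0.25 ± 0.088 and thymosin beta a at 0.19 ± 0.075. The list of cell cycle genes had 2 probes and was not tested; cdc23 stood at 0.064 ± 0.057 and a CDK5 activator at -0.029 ± 0.061, above 0 after median centring.

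Markers of other cells were measured because dispersed pituitaries can hold blood, nerve endings and connective tissue. The 12 red blood cell probes had a median of 0.068, with 9 above 0 and 3 below (adjusted p = 0.235, camera, and 0.0236 after median centring), with alpha-globin at 0.15 ± 0.065 (SE, 4 arrays), a hemoglobin beta chain at -0.10 ± 0.058 (its 3 probes averaged -0.015) and a beta-globin probe not well above background in control cells. The 52 leukocyte probes had a median of -0.016 (adjusted p = 0.235, camera). MHC class I probes 14n21 and 21f13 stood at -0.29 ± 0.085 and -0.34 ± 0.10 and an invariant chain-like protein at -0.25 ± 0.078. Probe 21f13 passed only without replicate 4, where replicate 2 is alone in its dye orientation. All 6 MHC class I probes averaged -0.083 ± 0.087 (SD, 4 arrays), 0.043 on replicate 3, with 4 below 0 and 2 above, and the 11 invariant chain-like probes averaged -0.068. The 77 neural and glial probes had a median of 0.017 (adjusted p = 0.296), where EPD-I probe 42f12 stood at 0.21 ± 0.071 and EPD-I probe 42i24 was not well above background in either group; the 6 EPD-I probes averaged 0.083. The 103 muscle probes had a median of 0.0038 and a mean of -0.0049, with camera pointing down (adjusted p = 0.727); a myosin light chain 3 probe stood at -0.25 ± 0.073 (12 such probes averaged -0.11), troponin C at -0.20 ± 0.074, and troponin I was not well above background in control cells.

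For connective tissue and endothelium, 7 probes had a median of 0.058 (adjusted p = 0.437, camera). Vimentin probe 24i24 stood at -0.13 ± 0.12 (SE, 4 arrays), the 5 vimentin probes averaged 0.0028, and vimentin probe 14j12 and collagen alpha 1(I) were not well above background in control cells. Collagen alpha 1(I) and claudin-4 passed only without replicate 4. That fit leaves replicate 2 alone in its dye orientation, so the spread of such a value was not measured. For epithelium, 6 probes had a median of -0.028 (adjusted p = 0.469), with a claudin-4 probe at -0.37 ± 0.20 (its 2 probes averaged -0.19), claudin-20 at -0.040 ± 0.075 (above 0 without background correction and in the authors' table) and claudin-23 not well above background in control cells. For liver, 10 probes had a median of -0.010 and a mean of -0.0038 while camera pointed up (adjusted p = 0.727). Apolipoprotein A-IV probes 17g01 and 15k08 and fibrinogen-like protein 1 were not well above background in control cells. Over the 24 lists, 0 members passed in limma over all genes and 0 adjusted over the list alone; of the ribosomal protein probes, for example, 6 were lower at an unadjusted p under 0.05.

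The exchange of dyes also allowed a test of dye effects. Growth hormone had a Cy5 over Cy3 ratio of 0.44 on the log2 scale and the somatotropin probe one of 0.36, and elongation factor 1 alpha stood at 0.24. Over all 8089 probes limma called 0 with a dye effect, with a smallest adjusted p of 0.716, beside 270 probes brighter in Cy5 and 269 brighter in Cy3 at an unadjusted p under 0.05. After median centring that split was 162 and 475. Limma called 433 probes without replicate 2 (394 brighter in Cy5, 39 in Cy3) and 324 without replicate 4 (34 and 290).

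The array pairs were compared over all probes, which are not independent replicates. Replicates 2 and 4, both with secretoneurin in Cy3, opposed each other at Pearson's r = -0.61, and at -0.80 among the brightest 20% of probes. In the authors' deposited table the value was -0.38. Replicates 1 and 3 correlated at 0.25, replicates 3 and 4 at -0.25, replicates 1 and 4 at -0.11, replicates 2 and 3 at 0.11, and replicates 1 and 2 at -0.0057. The 2 spots of a clone on the same array correlated at 0.12, 0.54, 0.20 and 0.71 on replicates 1 to 4. Such correlations also depend on the spread of the ratios between probes, with SDs of 0.20, 0.32, 0.19 and 0.38 on replicates 1 to 4. They therefore do not rank the arrays by the noise between spots. The labels and the file headers state the dyes of every array, so the stated direction was kept. Turning the sign of replicate 4 or of replicate 2 was an alternative added after the data were seen. Either turn leaves 1 array alone in its sign, and beside the dye effect that array adds nothing to the residual. The counts of probes from these fits therefore cannot weigh an exchange and are not set beside those of the stated signs.

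**Figure D3:**
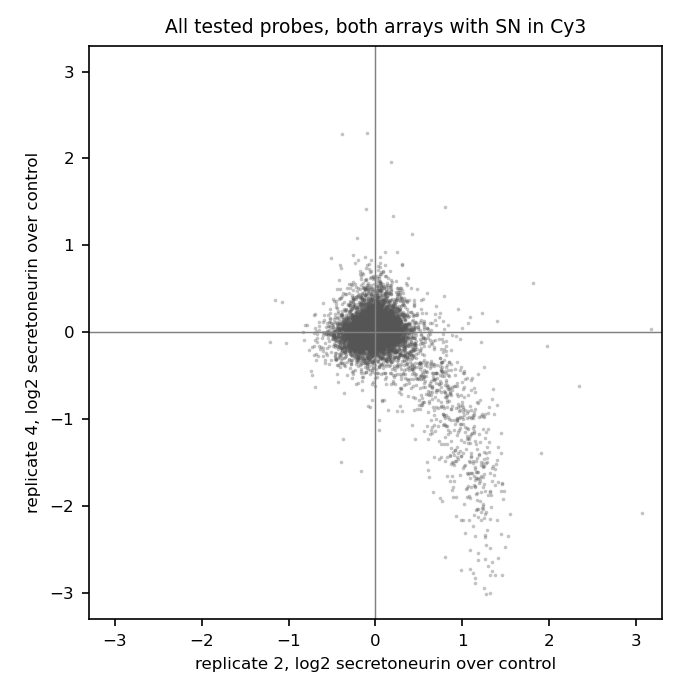
Log2 ratio of secretoneurin over control on replicate 2 (x axis) against replicate 4 (y axis), both with secretoneurin in Cy3; each point is a tested probe. A group of probes lies above 0 on replicate 2 and below 0 on replicate 4, and the correlation over all probes is -0.61.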

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

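The comparison of salmon sperm DNA spots was chosen only after the result was seen, and the search for single arrays far from the others followed a fixed rule. Of 93 named probes with 4 values, 3 had 1 array far from the others, where chance gives about 1 in 20 sets of values, and of the 24 lists and 5 measures of array quality 0 did. The glutathione S-transferase alpha 1 probe stood at -0.50 on replicate 2, against -0.061, -0.035 and -0.036 on replicates 1, 3 and 4. Claudin-4, a tight junction protein, stood at -1.22 on replicate 2, against -0.16, 0.024 and -0.11 on the other arrays. Both probes were near background, so these ratios are uncertain. Claudin-4 was above it on 1 array in each group, and the glutathione S-transferase probe on 1 array in secretoneurin and 2 in control cells. The probe of initiation factor 4 gamma 1 had ratios of -0.50 on replicate 1 and -0.21, -0.17 and -0.19 on the others, but its control signal was not well above background on any array, so these are not measured folds.

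Signal also appeared in spots outside the comparison. Of the salmon sperm DNA spots, usually printed as a control for unspecific hybridisation, 97.6% were above background in both channels over the 4 arrays, against 0.298% of the empty spots. Their median ratios of secretoneurin over control were -0.53, 0.34, -0.57 and 0.44 on replicates 1 to 4, which is brighter in Cy3 on all 4 arrays.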

How the results depend on the processing

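The turned signs of replicates 4 and 2 were settings chosen after the data were seen. The count of 0 probes changed by secretoneurin held in all 14 planned settings that kept 4 arrays, with 22 to 397 probes at an unadjusted p under 0.05 in limma or the unmoderated test. Leaving out single arrays gave 0 to 438 probes, and 0 to 433 with a dye effect; without replicate 2 or 4 the remaining array of that orientation is alone and is assumed to vary like the others. With no dye effect as well, an added setting, all 4 such counts were 0. With the sign of replicate 4 or 2 turned, 1 array is alone in its sign and adds nothing to the residual, so those counts are not compared. The ribosomal protein list lost its call with an adjusted p of 0.0950 among probes above background (82 probes, median -0.058 against -0.051), 0.600 with an estimated correlation, 0.326 with replicate 4 turned and 0.0565 with replicate 2 turned, and ran from 0.000672 to 0.255 with single arrays left out. The estimated correlation was 0.012, close to the preset 0.01, but that test rests on 2 residual degrees of freedom and called 0 lists. Fry, which asks another question, gave 0.833, and 0.950 for mixed directions. Granins gained a call after median centring (0.000774) and with 1 probe per gene name (0.0442), as did translation factors with 1 probe per gene name (0.0442) and red blood cell markers after median centring (0.0236). The antioxidant and iron list gained one with replicate 2 turned (0.0117) and ran from 0.00264 to 0.889 with single arrays left out. The cause was not tested. Of 428 list values under alternatives, 413 kept their side of the threshold; 38 uncalled ones had the other direction. Of 1525 values of named probes, 0 with an unadjusted p under 0.05 or a call changed sign, 44 others did, and 5 passed the threshold, all with replicate 2 or 4 left out. The planned change between mean and median pixel values was not run. Of 8089 probes 839 were above background in both channels on all 4 arrays, and among these too 0 were called.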

Other observations

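Apart from the correlation between probes of one gene name on different source plates and the sign patterns of the ribosomal list, the tests here were chosen only after the result was seen, as were the groups of probes named in the next sentences. The 6 dopamine receptor probes had a mean log2 ratio of 0.14 ± 0.046 (SD, 4 arrays) and stood at 0.18, 0.08, 0.17 and 0.13 on replicates 1 to 4, with 4 probes above 0 and 2 below. Of the 6, only 2 were above background in both groups on at least 1 array, so this mean is not a measured fold. In the authors' deposited table the 6 probes averaged 0.19, -0.013, 0.40 and 0.014 on replicates 1 to 4. Calmodulin, with 28 probes, had a mean of -0.032 ± 0.023 (SD, 4 arrays), with 20 probes below 0 and 8 above. The 10 HSP90-beta probes averaged -0.091 ± 0.083 (SD, 4 arrays), with 9 below 0. Ependymin probes numbered 33 and averaged 0.038 ± 0.068 (SD, 4 arrays), and the 14 GAPDH probes averaged -0.046 ± 0.055 (SD, 4 arrays), each with both signs among the arrays. The means of these 5 groups kept their signs under every scaling tried and in the authors' deposited table, but not their sizes: with print-tip loess the dopamine receptors averaged 0.073 and ependymin 0.0068, and after median centring GAPDH averaged -0.10, HSP90-beta -0.15 and calmodulin -0.056. Signs on single arrays were not always kept.

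Replicates 2 and 4 had opposite ratios, with a correlation of -0.61 over all probes, and the Cy3 oligo spots, with a Cy5 over Cy3 of -1.97, -2.22, -2.31 and -1.73 on replicates 1 to 4, argue against exchanged images of replicate 4. The 261 probes called lower without replicate 2 and higher without replicate 4, a choice that makes these arrays opposed in them, were unevenly spread over the 34 source plates with at least 50 probes (permutation p = 1e-04 at matched brightness, the smallest that 10000 permutations can give): 5 plates with 1760 probes held 0 where 26.7 were expected, so a candidate explanation is a property of the clones of certain plates. Transcripts that differed between the cultures stay open, since the difference correlated at r = 0.244 (Spearman's rho = 0.162, permutation p = 0.0148 for r) over 95 gene names with probes on different plates, below the 0.3 set for it. Of 15 such pairs with at least 1 of the 261 probes, 2 had both among them, and the difference divided by 2 had a median of 0.19 over the partners, against 1.34 over the 261 probes, which were selected for it. An exchange of the RNAs of replicate 4 before labelling stays open too: with its sign turned its 3 pairs correlated at 0.106 or more, but a dye effect shared by the arrays would also raise those with replicates 1 and 3.

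The lower ribosomal protein probes had a median Cy5 over Cy3 ratio below 0 on all 4 arrays, at -0.22, -0.08, -0.14 and -0.07, as a dye effect stronger on replicates 1 and 3 would give. A shared secretoneurin response beside a dye effect of equal strength would give the same: in all 4 pairs of arrays of opposite dye orientation the mean of the medians was below 0, from -0.074 to -0.031. These explanations cannot be told apart, since secretoneurin carried Cy5 on both arrays with the stronger ratios. The list was also bright: 82 of its 115 probes were above background in both channels on all 4 arrays, against 839 of all 8089. After median centring without loess its median was -0.14 (adjusted p = 8.83e-16, camera). Among probes above background its median was -0.058 (adjusted p = 0.0950, camera). A link of the shift to brightness was not tested. Of the 7 sign patterns that the model can fit, 1 gave a camera p as small as the real 2.72e-05, with 0.000299 the nearest other, and 7 patterns are too few for a share under 0.05.

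The secretogranin II probe 17o09, with ratios below 0 on all 4 arrays, stood apart from the other 6 probes of that name. Their mean log2 ratio was -0.022 ± 0.020 (SE, 4 arrays), with 4 below 0 and 2 above. Probe 17o09 was left out as that of smallest p, which moves this mean toward 0. All 7 probes averaged -0.055 ± 0.057 (SD, 4 arrays). Both means argue against a change of the secretogranin II transcript by the -0.25 of that probe, but not against a smaller one. A gene copy measured by that probe alone stays open and was not tested.

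The count of probes changed by secretoneurin was at least as large as the real 0 in 7 of 7 sign patterns, with 1 the highest other; a real count of 0 fixes that outcome, and the patterns are too few for a share under 0.05. At an unadjusted p under 0.05 limma gave 224 probes for the real pattern, and 360 and 194 for the others with equal numbers of arrays in each sign. The remaining patterns, among them that with replicate 4 turned, leave 1 array alone in its sign. Such an array adds nothing to the residual, so those counts are not compared.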
